A study of Homo sapiens with 6 samples.

How the data were processed

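RNA was sequenced from H1299 cells, an established line from a human non-small cell lung cancer, 48 h after transfection with control siRNA (siCtrl) or with siRNAs against IQGAP3 (siIQGAP3). Per the labels' protocols, RNA was isolated with Trizol, libraries were made with an Illumina mRNA-seq kit and sequenced as read pairs on an Illumina HiSeq instrument. Each group holds 3 samples, which the series' design text calls independent without saying whether they were separate cultures. The limma p-values for genes thus measure the spread between these samples, which may be technical. The siRNA sequences, and how many IQGAP3 siRNAs were pooled, are not given in the sources used here. The submitters' processing notes name StringTie 1.3.3b and the GRCh38 genome build. The aligner, the counting tool and whether counting used strand are not given in the sources used here.

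Each library's table has 1 value for each of 48642 loci, of which 25200 carry an Ensembl gene identifier and 23442 an assembled locus identifier. Of the assembled loci, 20328 name no known gene, and 1355 loci of the table merge several known genes. The deposited values are in RPKM, a unit settled from the values because the column headings name only a sample. They summed to between 239053 and 244233 per library, and for 48640 of 48642 loci a gene length of up to 120000 bp turned all 6 values into whole reads within a tolerance of 0.0001. That length equalled the annotated exon length in 761 of 840 genes with a single transcript and over 100 reads. Whether those whole numbers are reads, read pairs (which would make the unit FPKM) or rounded estimates is not given in the sources used here. The value columns of 2 control libraries carry a different prefix from their titles, and their samples were taken from the series record. Genes with a coordinate in the tables were matched by identifier to GENCODE release 29, in which 26512 of 26917 matched genes (98.5%) had the same coordinates.

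The value of 1 read implied totals of 32729595, 33036500 and 34098024 reads for the siIQGAP3 libraries and 33403959, 33743832 and 35312863 for the siCtrl libraries, and the recovered whole reads summed to at least 99.68% of these totals. A value of 0.0283 to 0.0306 RPKM corresponded to 1 read in a gene of 1 kb. Intervals and p-values do not account for duplicate reads.

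The plan set before the data were examined foresaw TPM, or FPKM in its absence. The values proved to be RPKM and were used as deposited in the same test, with limma 3.58.1 in R 4.3.3 (moderated statistics with a mean-variance trend) on log2(RPKM + 1). Loci with a mean of at least 1 RPKM over the 6 libraries were tested, no replicate block was used, and Benjamini-Hochberg adjusted p-values under 0.05 were called changed. Fold changes on this scale are siIQGAP3 minus siCtrl and understate the change of genes with low values. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.

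The same plan fixed 30 gene lists, along with the rule for genes named in the text. The rule took IQGAP3, the 6 genes or complex members of the series title, and the 12 genes with the largest rise and the 12 with the largest fall among called genes with a mean of at least 5 RPKM in the higher group and groups that did not overlap. It also took up to 4 called members of each list, or, where none was called, up to 2 members with the highest level. Clones, pseudogenes, small RNAs and antisense genes were left out of the first part of that rule. Not every gene that the rule took is reported here. Lists with at least 5 tested members, 29 of the 30, were tested with limma camera at a preset correlation of 0.01. Members that the tables merge with a neighbouring gene were left out of the lists. Alternatives were an estimated correlation, fry, other pseudocounts, filters, scalings, limma settings and thresholds, protein-coding genes alone, the replicate number as a block, and each library left out in turn. After the data were seen, limma voom on the recovered reads, rescaling to TPM, loci with 1 known gene alone, merged loci counted as list members, removal of each library's trend with transcript GC content and length, and siCtrl-3 as the only control library were added.

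The same steps were tested on simulated data. Whole reads were drawn from the real means and library sizes, with the median spread between replicates given to every gene, 200 genes changed between siIQGAP3 and siCtrl, and 12527 loci past the filter. Of 50 genes per size, 40% were recovered at a fold of 1.3, 92% at 1.5, 98% at 2 and 100% at 3. Of 12327 unchanged loci, 8 were called, and 0 of 12483 were called when nothing was changed. In 20 draws with nothing changed, 0 lists were called. Genes were drawn independently of each other, so these draws do not tell how often lists of correlated genes are called in error. Duplicate libraries were sought with a chi-square statistic of the recovered reads, which lay between 23.7 and 39.0 per gene for every pair within a group, so no pair agreed within sampling noise.

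For 1 further test, all 7-nucleotide sequences (7-mers) were sought in the longest annotated 3′ UTR of at least 50 nucleotides of each tested protein-coding gene in GENCODE release 29, and 9165 genes had one, while 77 did not and were not searched. The log2 fold change, limited to 1.5 in either direction, was related to the presence of each 7-mer found in at least 30 UTRs, after removal of quadratic trends with UTR length and GC content. The result was set against a Bonferroni limit and 100 permutations of genes. Genes, not libraries, are the units of this scan, so its z and p-values do not measure the spread between libraries. In simulated data over 9165 genes, a planted fall of 0.1 ranked first in 10 of 10 draws, and 7 of 100 permutations held a 7-mer that went with lower values past the limit.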

Results

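Gene expression was compared between H1299 lung cancer cells transfected for 48 h with control siRNA and cells transfected with siRNAs against IQGAP3, a scaffold protein of the IQGAP family. There were 3 libraries per group, with 32729595 to 34098024 reads implied by the values of the siIQGAP3 libraries and 33403959 to 35312863 by those of the siCtrl libraries. Between 33985 and 35493 of the 48642 loci had a value above 0 in a library. The first principal component of log2(RPKM + 1) held 33.7% of the variance and separated the 2 groups. Mitochondrial transcripts took 2.12% to 2.44% of the recovered reads of a library.

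The first question was whether the target was lowered. IQGAP3 (ENSG00000183856, chromosome 1, 156525405 to 156572604, GRCh38) fell from 10.4 ± 1.16 RPKM in siCtrl to 3.64 ± 0.258 in siIQGAP3 (SD, n = 3 each). The 3 siCtrl libraries held 9.46, 11.7 and 10.1 RPKM and the 3 siIQGAP3 libraries 3.78, 3.80 and 3.34, so the mean was 65.1% lower. The log2 fold change was -1.30 ± 0.0879 (SE, limma adjusted p = 0.00257). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Against siCtrl-3 alone, a comparison with 1 control library whose spread comes from the siIQGAP3 libraries, the log2 fold change was -1.27.

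The series title names RAD17, the MRN complex, ATM and Chk2, a pathway that senses and signals DNA breaks. The second question was whether the transcripts of these genes moved with IQGAP3. RNA levels do not measure the proteins or the activity of that pathway. RAD17 (ENSG00000152942, chromosome 5, 69369293 to 69414801), which loads the checkpoint clamp at damaged DNA, fell from 9.17 ± 0.238 to 4.43 ± 0.533 RPKM (SD, n = 3 each). Its log2 fold change was -0.91 (limma adjusted p = 0.00457). The nuclease gene MRE11 was at 7.51 ± 0.624 RPKM in siCtrl and 6.04 ± 0.123 in siIQGAP3 and missed the threshold (limma adjusted p = 0.0759). MRE11 passed it with each library's trend with GC content and length removed (limma adjusted p = 0.0377, in a range of 0.0377 to 0.569 over 21 alternatives). The other 2 MRN genes did not pass, with log2 fold changes of 0.01 for RAD50 and -0.15 for NBN (limma adjusted p = 0.961 and 0.462). The kinase genes ATM and CHEK2 did not pass either, with log2 fold changes of -0.26 and 0.05 (limma adjusted p = 0.208 and 0.754). RAD17 stayed past the threshold with each library left out, with log2 fold changes between -0.98 and -0.84. It missed the threshold with the replicate number as a block (log2 fold change -0.91, limma adjusted p = 0.0644). Against siCtrl-3 alone, where the spread comes from the siIQGAP3 libraries, the log2 fold change of RAD17 was -0.94. The 512-nucleotide annotated 3′ UTR of RAD17 holds both of the 7-nucleotide sequences, GCCAAAT and GAGTGGT, that ranked first and second of 16287 for lower log2 fold changes across genes. The longer UTR of MRE11 (4550 nucleotides) holds GAGTGGT and AAGTGGT, and that of ATM (3597 nucleotides) holds GTAAATC, further sequences that went with lower values. The UTRs of RAD50, NBN and CHEK2 hold none of these sequences, nor GCACTTT, which ranked first for higher log2 fold changes across genes. That of CHEK2 has 157 nucleotides, so it offers little room for any. The UTRs of MRE11 and ATM do hold GCACTTT, and that of RAD17 holds CACTTTA, which ranked second for higher values. Opposite-strand genes overlap 9.1% of the exon bases of RAD17. The level of RAD50 is uncertain, since other annotated genes overlap 79.7% of its exon bases.

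**Figure D1:**
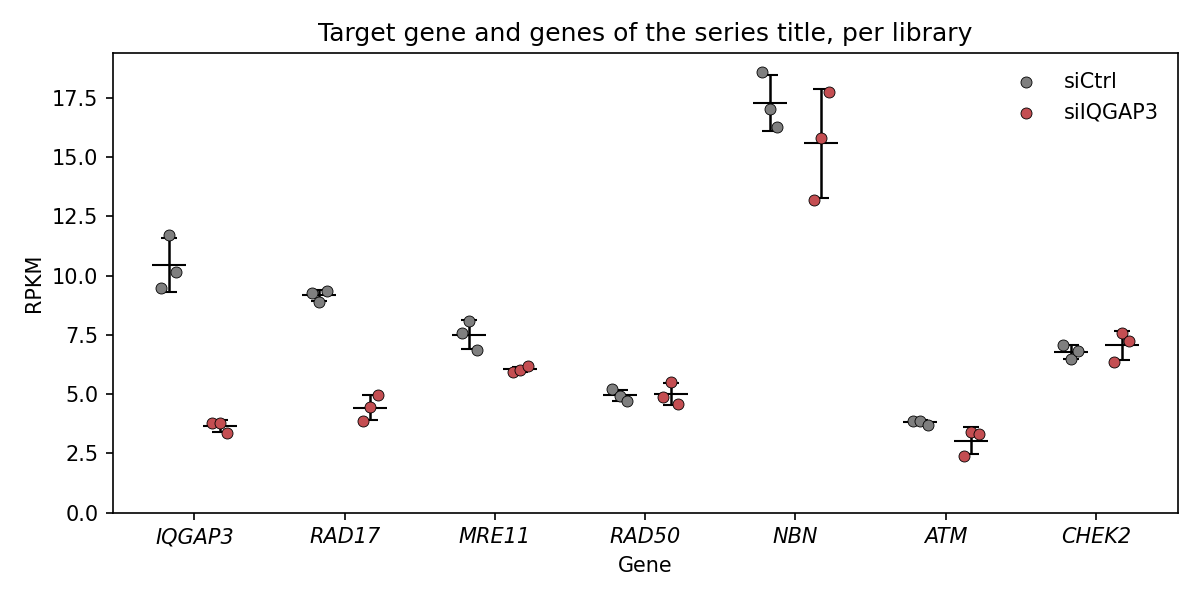
RPKM of IQGAP3 and of the genes of the series title in each library (points), with the mean and SD of the 3 libraries per group (bars). The siIQGAP3 libraries of IQGAP3 (3.34 to 3.80), RAD17, MRE11 and ATM lie below all siCtrl libraries, while the groups of RAD50, NBN and CHEK2 overlap. Over all tested loci the groups did not overlap in 30.6%.

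Across 12485 loci tested, 656 (5.25%) differed between siIQGAP3 and siCtrl, with 277 higher and 379 lower. Most changes were small: the median log2 fold change was 0.38 among the higher and -0.44 among the lower loci, and 3 rose and 10 fell by at least 1 on the log2 scale. Among genes that rose, CCND1, which encodes the G1 cyclin D1, went from 48.5 ± 6.77 to 94.4 ± 19.6 RPKM, a log2 fold change of 0.94 (limma adjusted p = 0.0308). LIN28B, an RNA-binding protein that blocks let-7 microRNA maturation, rose from 24.1 ± 0.610 to 43.4 ± 5.43 RPKM, and the small GTPase gene RHOB rose by 0.72 on the log2 scale (SD, n = 3 each). The kinase gene HIPK3 rose by 0.89 on the log2 scale and the fibronectin receptor subunit ITGA5 by 0.64. ENO2 (neuronal enolase), ZNF367, CHAC1 (a glutathione-degrading enzyme), TBC1D9, ORC6 (a subunit of the replication origin complex), HIC2 and KRTAP2-3 rose by between 0.60 and 0.79. Of these 12 genes, HIPK3, LIN28B, RHOB, TBC1D9 and HIC2 stayed called with each library left out, while CHAC1 lost the call in all 6 omissions, CCND1, ENO2, ZNF367, ORC6 and KRTAP2-3 in 5 of 6, and ITGA5 without siCtrl-2. The 3′ UTRs of CCND1, ENO2, ZNF367, TBC1D9 and ORC6 hold GCACTTT, the 7-nucleotide sequence that ranked first for higher log2 fold changes across genes. Of the 12 largest falls described next, 4 hold it as well.

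Among genes that fell, VGF, which encodes a secreted neuropeptide precursor, held 18.8, 4.46 and 3.26 RPKM in the siIQGAP3 libraries against 59.9, 41.4 and 55.3 in siCtrl, a log2 fold change of -2.77 (limma adjusted p = 0.0429). The call of VGF was lost when any library but siIQGAP3-1 was left out. ANP32E, a chaperone of the histone variant H2A.Z, fell from 49.2 ± 2.73 to 18.7 ± 1.70 RPKM, a log2 fold change of -1.35. The replication factor gene GINS4 had a log2 fold change of -1.30 and KHNYN of -1.20, and opposite-strand genes overlap 23.6% and 29.3% of their exon bases. HSPB1, the small heat shock protein HSP27, fell from 239 ± 12.4 to 109.9 ± 1.89 RPKM (n = 3 each, limma adjusted p = 0.000581). RAD21, a cohesin subunit, fell from 77.5 ± 1.62 to 36.0 ± 1.89 RPKM (n = 3 each, limma adjusted p = 0.000605). DHTKD1, PCNP, the Wnt inhibitor DKK1 and the myosin MYO1C fell by between 0.90 and 1.08. Opposite-strand genes overlap 10.3% of the exon bases of CCND1 and 9.6% of those of DKK1, and other genes overlap 14.2% of those of RAD21. Together with IQGAP3 and RAD17 these make up the 12 largest falls under the rule for named genes, of which all but VGF stayed called with each library left out. The annotated 3′ UTRs of 8 of the 12 hold at least 1 of 5 leading 7-nucleotide sequences that went with lower values across genes, as do those of 5 of the 12 largest rises. These sequences were ranked on all genes searched, these included, so such counts are no independent comparison, and 1 of the 5, CCCATAA, had a z of -5.08, which did not pass the lowest of 100 permutations (-5.11). The UTRs of IQGAP3, VGF, GINS4 and HSPB1 hold none of the 5.

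**Figure D2:**
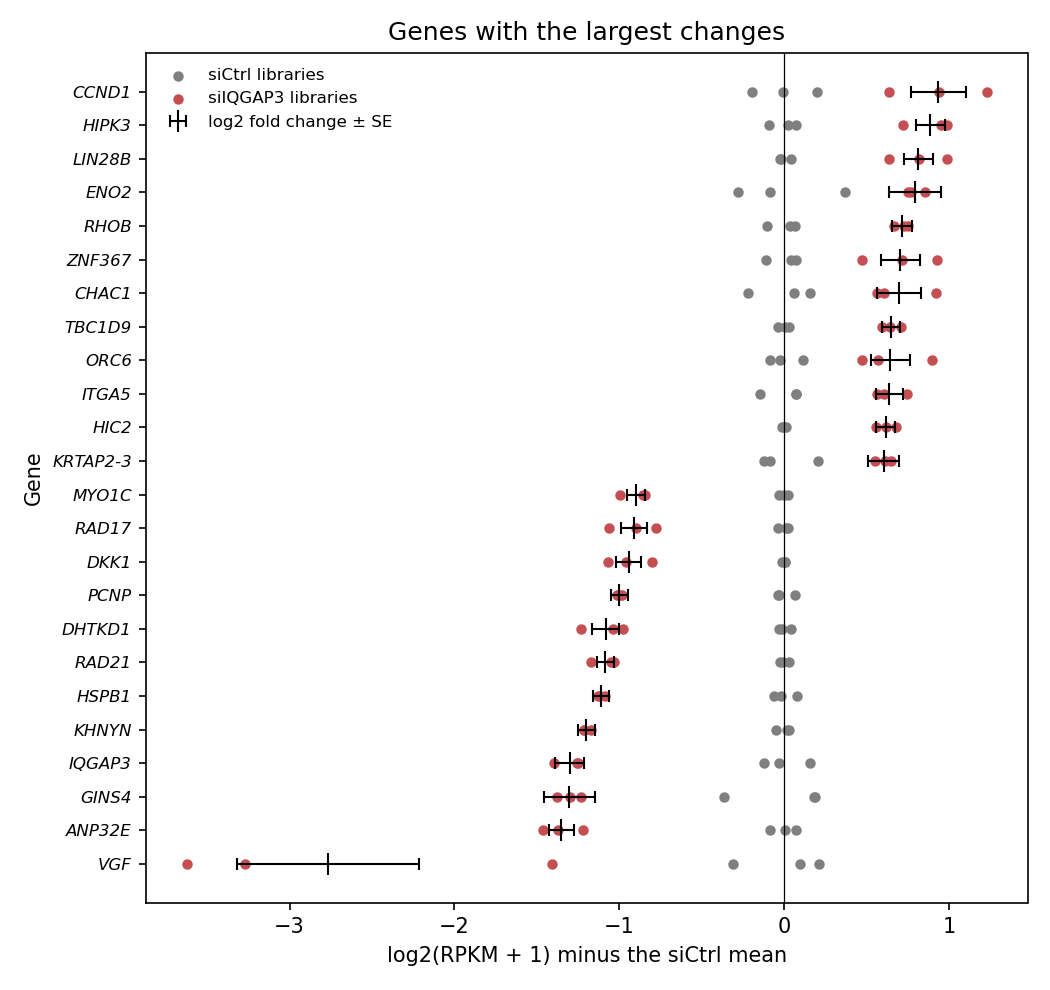
The 12 genes with the largest rise and the 12 with the largest fall under the rule for named genes, as log2(RPKM + 1) of each library minus the siCtrl mean (points), with the log2 fold change and its SE (black). The 3 siIQGAP3 libraries of each gene lie on 1 side of the 3 siCtrl libraries, and those of VGF spread the most.

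The count of changed genes moved by over 1.5 times with 5 of the 6 libraries left out in turn: it was 173 without siIQGAP3-2, 240 without siIQGAP3-3, 190 without siCtrl-1, 109 without siCtrl-2 and 157 without siCtrl-3, against 531 without siIQGAP3-1. It was 141 with no filter on low values and 13 with the replicate number as a block. Against siCtrl-3 alone it was 10, of which 2 were among the 656, with that library assumed to vary like the siIQGAP3 libraries. With each library's trend with transcript GC content and length removed it was 1150 of 10628 loci, against 677 of the same loci without that step.

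Of the 29 lists tested, camera with a preset correlation called 1 shifted up and 1 down, both with adjusted p = 0.547 with an estimated correlation. That estimate was -0.04 for the list shifted up, of ERK targets, and 0.19 for the list shifted down, of cholesterol synthesis. The preset was 0.01, so the ERK list did not lose its call through a higher correlation. Camera with an estimated correlation also works with the few degrees of freedom left by 6 libraries, so fewer lists can pass it. Its loss of both calls therefore does not decide whether these lists moved. Among targets of the ERK pathway, 20 of 24 members had a higher mean log2 value in siIQGAP3, and 4 rose and 1 fell (6 rose and 1 fell adjusted over the list alone). EGR1, an immediate early transcription factor, rose from 7.96 ± 0.135 to 11.5 ± 1.56 RPKM and the feedback inhibitor gene SPRY2 from 23.5 ± 0.642 to 32.5 ± 2.15 (n = 3 each). CCND1 and IER3 rose too, and TGFA, a ligand of the EGF receptor, fell by 0.43 on the log2 scale. The list's camera test gave an adjusted p = 0.0133, but 0.0927 over genes with a mean of at least 5 RPKM, in a range of 0.000339 to 0.547 over 24 alternatives. Among genes of cholesterol synthesis, 19 of 22 members were lower, and 4 fell and 0 rose (8 fell and 1 rose adjusted over the list alone). The reductase gene DHCR7 fell by 0.67, the sterol isomerase gene EBP by 0.46, the cyclase gene LSS by 0.43 and the thiolase gene ACAT2 by 0.24 on the log2 scale, with ACAT2 going from 46.2 ± 1.79 to 38.8 ± 1.32 RPKM (SD, n = 3 each). The list's median log2 fold change was -0.17 (camera adjusted p = 0.00134, and 0.0644 by fry, in a range of 4.18e-06 to 0.547 over 24 alternatives). Opposite-strand genes overlap 52.3% of the exon bases of ACAT2.

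Of 21 tested members of the list of MRN, ATM, CHK2 and RAD17 signalling, 1 fell, RAD17, both over all genes and adjusted over the list alone, and 0 rose (camera adjusted p = 0.525). Of 31 homologous recombination and Fanconi genes and 13 end-joining genes, 0 rose and 0 fell under both adjustments (camera adjusted p = 0.688 and 0.656). By limma, 10 and 2 members of these lists had an unadjusted p under 0.05, and voom called 0 in both. Over all 12485 tested loci, 2905 had an unadjusted p under 0.05, the share against which such counts, here and below, are to be read. The single-strand binding protein gene RPA2 was at 59.2 ± 2.50 RPKM in siCtrl and 70.8 ± 3.32 in siIQGAP3 and missed the threshold (limma adjusted p = 0.0517). Of 22 p53 targets, 4 rose and 0 fell (4 rose and 1 fell adjusted over the list alone): SESN2 and SESN1, which encode stress-induced sestrins, by 0.54 and 0.43, the death receptor gene TNFRSF10B by 0.30 and CCNG1 by 0.22 on the log2 scale (camera adjusted p = 0.312). Of 25 apoptosis regulators, TNFRSF10B rose and 0 fell (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.656).

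Of 37 genes of G1/S and DNA replication, GINS4 and MCM6 fell and ORC6 rose (3 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.167). MCM6, a helicase subunit, fell from 74.2 ± 2.01 to 64.3 ± 0.270 RPKM. Of 41 genes of G2/M and mitosis, the kinase NEK2, cyclin A (CCNA2) and the anaphase activator CDC20 fell by 0.62, 0.40 and 0.37 on the log2 scale, and 0 rose (5 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.406). Of 14 replication-dependent histones, 0 changed over all genes and 2 fell adjusted over the list alone (camera adjusted p = 0.167), while 6 had an unadjusted p under 0.05 by limma and voom called 0.

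Among 20 mesenchymal and invasion genes, the intermediate filament gene VIM fell from 723 ± 8.75 to 400 ± 10.7 RPKM (n = 3 each, limma adjusted p = 0.000581), ITGAV and PLAU fell by 0.44 and 0.43 on the log2 scale, and ITGA5 was among those that rose (3 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.688). Opposite-strand genes overlap 24.4% of the exon bases of VIM and 31.1% of those of PLAU. Among 32 actin and focal adhesion genes, CNN3 (calponin), PFN1 (profilin) and DIAPH3 (a formin) fell by 0.62, 0.37 and 0.35 and MYL12B rose by 0.21 (3 fell and 4 rose adjusted over the list alone, camera adjusted p = 0.688). Among 18 YAP and TEAD targets, CTGF and LATS2 rose by 0.47 and 0.40, and IGFBP3 and MYOF fell by 0.68 and 0.34 on the log2 scale (3 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.688). Among 22 TGF-beta targets, KLF10 rose by 0.39, and THBS1 and TGFBI fell by 0.39 and 0.35 (1 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.688). Of 6 Wnt targets, DKK1 fell (1 adjusted over the list alone, camera adjusted p = 0.167). Of 20 genes of IQGAP family members and partners, with IQGAP3 itself left out, 0 changed under either adjustment (camera adjusted p = 0.891), 4 had an unadjusted p under 0.05 by limma and voom called 0. RHOA was at 161 ± 8.37 RPKM in siCtrl and 186 ± 17.8 in siIQGAP3 (limma adjusted p = 0.183), and CDC42 was at 98.7 ± 3.23 and 105 ± 7.86 RPKM, with 59.4% of its exon bases overlapped by other genes. Of 5 epithelial genes, 0 changed under either adjustment (camera adjusted p = 0.767), with 0 at an unadjusted p under 0.05 by limma and 0 called by voom.

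Among stress and metabolic lists, HSPB1 and HSP90AB1 were the members that fell of 14 heat shock and immediate early genes (5 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.205). Of 30 genes of the integrated stress and unfolded protein response, CHAC1 rose and the serine synthesis gene PSAT1 fell by 0.53 (3 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.741). Of 21 hypoxia and glycolysis genes, ENO2 rose and the hexokinase gene HK2 fell by 0.53 (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.741). Of 17 NRF2 targets, the haem oxygenase gene HMOX1 rose by 0.44 and UGDH fell by 0.28 (1 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.688). Of 24 lysosome and autophagy genes, 18 had a higher mean log2 value in siIQGAP3 but 0 passed the test under either adjustment (camera adjusted p = 0.167), with 5 at an unadjusted p under 0.05 by limma and 0 called by voom.

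Of 23 interferon response genes, TAP1 fell by 0.39 (1 adjusted over the list alone, camera adjusted p = 0.526). Of 13 NF-kB targets, NFKB2 and NFKBIE fell by 0.29 and 0.23 on the log2 scale (2 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.525). Of 12 genes of small RNA silencing, AGO4, an Argonaute gene, rose from 3.13 ± 0.0642 to 3.94 ± 0.126 RPKM (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.963). Of 42 ribosomal protein genes and 6 mitochondrially encoded genes, 0 changed under either adjustment (camera adjusted p = 0.656 and 0.688), with 0 at an unadjusted p under 0.05 by limma and 0 called by voom in both. Of 5 lung epithelial and neuroendocrine markers, ENO2 rose (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.994). The marker list of fibroblasts, endothelium and blood had 1 tested member, COL1A1, too few for camera. COL1A1 held 0.0396, 0.0785 and 2.24 RPKM in siCtrl and 2.19, 2.52 and 2.83 in siIQGAP3 and missed the threshold (limma adjusted p = 0.164, and 1 call when adjusted over that list alone). COL1A2 and COL3A1, of the same list, lay below the filter. COL1A2 had 466, 528 and 671 recovered reads in siIQGAP3 and 472 in siCtrl-3, and COL3A1 had 234, 283 and 387 and 296, while both were listed at 0 in siCtrl-1 and siCtrl-2. These genes, SPARC, DCN and LUM were chosen after their values were seen. SPARC, a collagen-binding protein of the mesenchymal list, held 1.56, 1.61 and 2.00 RPKM in siIQGAP3, 1.65 in siCtrl-3, and 0.310 and 0.227 in siCtrl-1 and siCtrl-2 (limma adjusted p = 0.191). DCN and LUM were at 0.218 ± 0.0382 and 0.159 ± 0.121 RPKM in siIQGAP3 and at 0.0560 ± 0.0586 and 0.0188 ± 0.0326 in siCtrl (SD, n = 3 each). Of 7 genes that mark H1299 identity, 0 changed under either adjustment (camera adjusted p = 0.656), with 0 at an unadjusted p under 0.05 by limma and 0 called by voom. The median and mean of a list differed in sign for the integrated stress, small RNA silencing and lung epithelial lists. With an estimated correlation, a setting that fewer lists can pass, 0 of the 29 lists were called. Fry, which asks whether a list's own genes move on balance one way, called 6. These were the ERK, G1/S, p53 target, NF-kB, Wnt and heat shock lists.

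**Figure D3:**
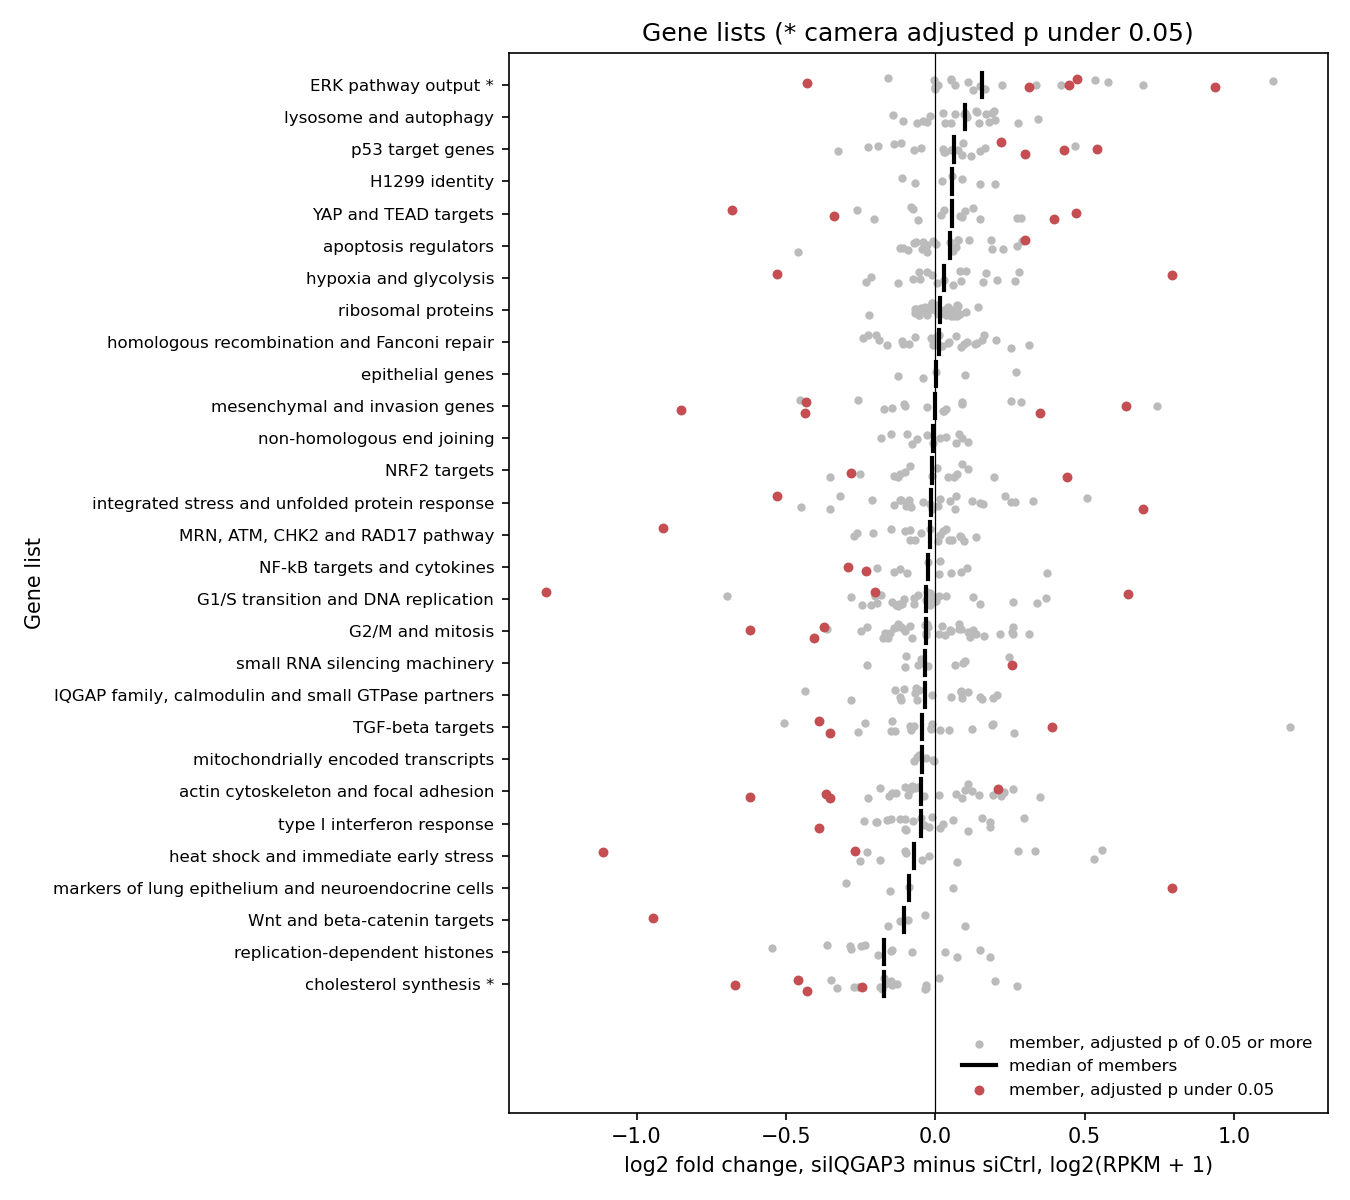
Log2 fold change of each tested member (points) of the 29 lists, siIQGAP3 minus siCtrl on log2(RPKM + 1), with the list median (black bar) and members past the threshold in red. An asterisk marks the 2 lists past the camera threshold, ERK pathway output (higher) and cholesterol synthesis (lower, median -0.17).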

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

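The voom, TPM, 1-known-gene, merged-locus, GC-and-length and single-control alternatives were chosen after the data were seen. The IQGAP3 level stayed lower under all 21 alternatives run, with log2 fold changes of -1.52 (voom) to -1.22, and past the threshold in 20 (all but siCtrl-3 as the only control). RAD17 kept its call in 19 of 21, all but the replicate block (limma adjusted p = 0.0644) and siCtrl-3 alone. With the block, 12 of the 12 largest rises and 4 of the 12 largest falls (VGF, GINS4, DKK1 and RAD17) lost their calls. CCND1, ENO2, ZNF367, CHAC1, ORC6, ITGA5, KRTAP2-3 and VGF lost theirs with no filter too. Against siCtrl-3 alone, the control library that holds collagen transcripts like the siIQGAP3 libraries, 10 changed (8 higher, 2 lower), and IQGAP3 had a log2 fold change of -1.27 (limma adjusted p = 0.0621). That comparison has 1 control library, and of the 24 largest changes HSPB1 kept its call. For named genes, 1776 values under alternatives gave 361 lost calls, 9 gained and 0 reversed, and for lists 694 gave 4 lost, 10 gained and 0 reversed. The groups of all 656 called loci do not overlap, so leaving out libraries could not turn their sign. Both other pseudocounts, a mean of at least 5 RPKM, both scalings, limma without trend or with robust eBayes, protein-coding genes alone, voom (613 calls shared), TPM and loci with 1 known gene moved the number of genes changed by less than 1.5 times (566 to 734). With no filter on low values 141 changed (38 higher, 103 lower) as 48642 loci were tested. An adjusted p under 0.01 left 106 (29 and 77), and a log2 fold change of at least 1 left 13 (3 and 10). With the GC and length trend removed 1150 changed (546 and 604). Leaving out 1 library, and so fitting fewer samples, gave 109 to 531 changed, 32 to 238 higher and 77 to 293 lower. The replicate block gave 13 (4 higher, 9 lower). Same-numbered libraries had correlations of -0.11, 0.04 and -0.13 and did not all correlate best with each other, so the numbers are not taken to pair the samples. The highest correlation, 0.19, was between siIQGAP3-3 and siCtrl-1, so a block on equal numbers may group unlike libraries. The number of lists called was 5 with no filter, 1 with a mean of at least 5 RPKM, 0 with an estimated correlation and 6 by fry. The cause of the moves in the GC and list counts was not tested. The planned run on FPKM as deposited was not made apart, since each table holds 1 value column. At this depth, with the median spread given to every gene, the simulation recovered 40% of changes of 1.3-fold, so small changes can go uncalled. Recovery in genes with a larger spread was not simulated.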

Other observations

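The tests here were chosen after the changed genes had been seen. What the 7-mer scan and the GC and length removal would have to show was written down before their results. The GC and length removal was run first over protein-coding genes and then over all loci with 1 known gene. The test of scaling, that of other splits, the choice of 5 leading 7-mers, the division by chromosome, the look at the RAD17 UTR and the loci of the next paragraph came after results or values were seen.

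VIM-AS1, antisense to VIM, held 3.56, 11.7 and 4.14 RPKM in siIQGAP3 against 37.7, 43.0 and 34.1 in siCtrl, a fall by 2.55 on the log2 scale (limma adjusted p = 0.0186). VIM overlaps 32.2% of the exon bases of VIM-AS1, and reads in these shared bases cannot be separated without strand. In 112 tested loci 1 library stood apart from the other 5 by over 0.8 on the log2 scale while those spanned under 0.4, below them in 80; they numbered 15 to 27 per library, and 0 of the 112 were among the changed loci.

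Genes that fell shared short sequences in their 3′ UTRs. Of 326 fallen genes with a searched UTR, 99 (30.4%) held GCCAAAT, against 11.4% of the genes not called and 6.9% of those that rose, and 24.8% held GAGTGGT, against 8.6% and 4.3%. The 7-mers were ranked on the same genes, so the shares of fallen and risen genes with or without them are no independent test. GCCAAAT ranked first and GAGTGGT second for lower values both on odd-numbered chromosomes (z = -10.5 and -7.47) and on the others (z = -9.36 and -7.24), whereas of 5 leading 7-mers AAGTGGT ranked 53 on the odd-numbered (z = -3.24) and CCCATAA 443 on the others. AAGTGGT stood in 17.2% of fallen genes against 12.8% of those not called, and the z of CCCATAA over all genes, -5.08, did not pass the lowest of 100 permutations. Relative to genes without it, genes with GCCAAAT deviated from the mean of all 6 libraries by -0.07, -0.03 and -0.03 on the log2 scale in the siIQGAP3 libraries and by 0.05, 0.04 and 0.03 in siCtrl. Genes fell in 6.9% of the 3274 UTRs with at least 1 of the 5 and in 1.7% of the 5891 with none, though the first are longer (median 2779 against 922 nucleotides).

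Library scaling and GC or length bias are argued against as the whole cause of the falls, since scaling would move all loci alike and the median log2 fold change was 0.00716 over all tested loci (interquartile range 0.221) against -0.44 over the fallen, while the GC and length trend held 0.451% of the variance of the log2 fold change and its removal kept 99.7% of the fallen genes with a GC value (91.3% of all fallen), with a median of -0.43 before and -0.44 after. A candidate explanation for part of the falls is that the IQGAP3 siRNAs lowered other transcripts through their seeds. Over 16287 7-mers the lowest z was -14.0 (GCCAAAT, Bonferroni-adjusted p = 2.64e-40), against -5.11 as the lowest of 100 permutations. Genes are the units of that scan, so this p-value does not measure the spread between libraries. The annotated IQGAP3 transcript, which holds 25.4% of all 7-mers, holds 3 of the 5 (GCCAAAT, GAGTGGT and AAGTGGT), the reverse complement of GTAAATC, as a match to a passenger strand would need, and CCCATAA in neither orientation. GAGTGGT and AAGTGGT share AGTGGT, so they may not count as separate matches. An effect of losing IQGAP3 itself was not tested and stays open, both for RAD17, whose UTR holds the leading pair as do 1.92% of those searched, and for genes with none of the 5, such as VIM and HSPB1.

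Of 233 risen genes searched, 102 (43.8%) held GCACTTT, the site of the miR-17 microRNA family, against 25.3% of the genes not called and 23.9% of those that fell. UTRs with GCACTTT are longer (median 2885 nucleotides, against 1405 over all searched). For higher values GCACTTT ranked 2 on odd-numbered chromosomes (z = 5.21) and 3 on the others (z = 4.26). Scaling and GC or length bias are argued against as the whole cause, as for the falls, with a median of 0.38 over the risen against 0.00716 over all tested loci, and with 98.8% of the risen genes with a GC value kept after trend removal (median 0.38 before and 0.37 after). The highest z was 6.72 (Bonferroni-adjusted p = 2.97e-07), against 4.96 as the highest of 100 permutations, a value consistent with lost repression by that family or with a control siRNA that has the same seed. Relative to genes without it, genes with GCACTTT deviated by -0.0002, 0.02 and 0.03 on the log2 scale in the siIQGAP3 libraries and by -0.005, -0.02 and -0.03 in siCtrl, in order of replicate number, so siIQGAP3-1 and siCtrl-1 showed almost no shift. The z takes genes as its units, so it does not measure that spread between libraries. Lost repression by the miR-17 family, a control siRNA with the same seed and an effect of IQGAP3 loss stay open. MicroRNA levels were not analysed here, and the siRNA sequences are not given in the sources used here.

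With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 656 changed genes and the highest other split gave 6, with 1 split of the 10 as large as the real one, namely itself.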
